A study of Mus musculus with 4 samples.

How the data were processed

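ATAC-seq peak lists of 4 libraries were analysed, 2 from WT and 2 from Sphk2 KO mice, per the labels' protocols from Gr1+CD11b+ cells sorted from ascitic fluid 14 days after EL4 injection. The labels call the libraries biological replicates but do not tie them to animals, so tests of peak numbers and similarity measured the spread between libraries. The other tests counted regions or genes and measured no such spread. Cutadapt, BWA, MACS2 and the mouse build mm10 are named in the submitters' processing notes, without versions or parameters. Per the file headers, peaks were called separately for each library with MACS 2.1.1.20160309 on paired-end fragments, without a control library, at a q-value of 0.05, with an effective genome size of 1.87e+09 and a local background of 10 kb. Per the file headers, 1 fragment per position was kept, which removed 6.42%, 8.23%, 8.24% and 8.99% of fragments in WT replicates 1 and 2 and Sphk2 KO replicates 1 and 2. Whether fragment ends were shifted for the Tn5 offset is not given in the sources used here, and a shift of a few bases would not alter overlap calls at the scale of peaks. No peak was listed on the mitochondrial genome.

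Each deposited list gives a peak's position, its pileup height (a coverage signal of fragments, not scaled to depth, per the file headers), the −log10 of its p-value and q-value as the authors' caller computed them, and its fold enrichment, a ratio of the authors' pileup over local background. The lowest −log10 q in every list was 1.30. These scores are each peak's own and depend on depth, so they were used only to describe, rank or filter peaks within a list. No read counts per region were used here, so comparisons rest on whether a peak was called. A region without a called peak may still be accessible below the threshold, and a library with fewer fragments yields fewer calls. Retained fragments ranged from 25877428 to 34443062, with fewer in both Sphk2 KO libraries. Median fold enrichment was 5.19 and 5.11 in WT replicates 1 and 2 and 6.03 and 6.01 in Sphk2 KO replicates 1 and 2. Depth and enrichment thus both differed between the genotypes.

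Peaks of all libraries that shared at least 1 bp were merged into regions, and a library had a region when any of its peaks overlapped it. WT-only regions had a peak in both WT libraries and in neither Sphk2 KO library, and Sphk2 KO-only regions the reverse. The same counts were made for the other 4 pairs of libraries. Coordinates are as the authors' files give them (mm10, counted from 1). Genes came from the RefSeq table for GRCm38.p6, the same assembly, with 21883 protein-coding genes. That table gives no strand, so the planned distance to a transcription start site was replaced by the distance to the nearer gene end, whichever end that was. A region was assigned to the protein-coding gene with the nearest end within 100 kb of its mean summit, and 441 genotype-specific regions had no gene within reach. The table gives no exons or introns, so peaks were classed as at a gene end (within 1 kb), inside a gene or between genes. A planned motif comparison needed a genome sequence and was not run.

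The number of peaks was compared by a two-sided exact permutation test and the base-pair Jaccard index by the 3 splits of the libraries into pairs. With 2 libraries per group neither test can give a p under 0.333. The 28 gene lists (558 genes, 556 found in the gene table, Mx1 and Mx2 not) were tested by two-sided Fisher's exact tests of WT-only against Sphk2 KO-only regions, each list against regions of all other genes, with Benjamini-Hochberg adjustment. Lists were drawn from general knowledge and some share genes, such as Klf4 and Irf8. Genes were named by rule: Sphk2 first, then the 12 genes per direction whose region ranked best by the worse of its 2 ranks by −log10 q, each within its own list, then up to 4 genes per list and direction. Further genes named by their gene-end peaks, and members of sets of 5 or fewer, were chosen after their values were seen. Some genes that the rule takes are not reported here. The grouping, the lists, the naming rule, the main tests and the other settings given next were set before the data were examined. Those settings were a −log10 q of at least 5, for presence alone or throughout, the same number of top peaks per library, windows of 250 bp around summits, autosomes only, peaks within 500 bp counted as present, other gene distances, and each library left out.

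Tests added after the data had been seen were the distribution over chromosomes, a −log10 q of at least 10 in both libraries, the share of genotype-specific regions among each list's regions called in 2 or 3 libraries, and gene-level tests. For the latter, genes with a peak within 1 kb of either end in both libraries of one group were split by whether neither library of the other group had one, and each list was compared with all other genes by Fisher's exact test. All such tests treat regions or genes as units, so their p-values describe these 4 libraries.

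Exact Clopper-Pearson intervals of shares cover counting error only. The steps were tested on simulated data. In peak lists simulated for the WT against Sphk2 KO comparison from 16933 real regions, with ends moved by up to 50 bp, all 200 planted WT-only and 100 planted Sphk2 KO-only regions were recovered with no other call. When 10% of peaks were dropped at random from each list, 82.5% and 80.0% were recovered, beside 127 and 149 calls that had not been planted. When the directions of 2293 genotype-specific regions were shuffled 200 times, the list test made a false call in 0 runs, and it called a planted list of 10 regions, 5 in each direction, in 200 runs. That list held an excess of Sphk2 KO-only regions, which made up 217 of the 2293. The check therefore says nothing about power for an excess of WT-only regions. In the gene-level step all 100 planted genes were recovered, beside 4 other genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.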

Results

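Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in myeloid-derived suppressor cells (MDSCs). These are immature myeloid cells that restrain T cell responses in tumour-bearing hosts. The cells carried the surface markers Gr1 and CD11b and were sorted from the ascitic fluid of mice 14 days after injection of EL4 cells, a mouse T cell lymphoma line. The mice were wild type (WT, n = 2 libraries) or lacked Sphk2 (Sphk2 KO, n = 2 libraries), the gene for sphingosine kinase 2, which makes the signalling lipid sphingosine 1-phosphate. The series title places the work in a study of how loss of this kinase alters lipid metabolism and the immune behaviour of MDSCs, and the comparison asks which regions were accessible in one genotype and not the other. Each library started from 20000 cells and 40% of the recommended Tn5. The authors' peak lists rested on 33859480 and 34443062 retained fragments in WT replicates 1 and 2 and on 25877428 and 27686223 in Sphk2 KO replicates 1 and 2.

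At the targeted gene, peaks showed a difference within the gene body. Sphk2 lies on chromosome 7 from 45709463 to 45718002 (mm10) and overlaps Rpl18, a ribosomal protein gene. A region at its upper-coordinate end, 45717303 to 45718352, was called in all 4 libraries, with the authors' −log10 q of 61.6 and 73.5 in WT and 28.0 and 70.5 in Sphk2 KO. A second region, 45715043 to 45716683, inside both Sphk2 and Rpl18, was called in both Sphk2 KO libraries (−log10 q 26.4 and 42.2) and in neither WT library. A neighbouring region inside Dbp, a circadian transcription factor gene, at 45706859 to 45708424 was called in all 4 libraries, with values of 8.90 and 12.6 in WT and 26.2 and 54.4 in Sphk2 KO. Another, at 45704400 to 45705339, had 26.9 and 30.6 in WT and 17.5 and 25.3 in Sphk2 KO. A peak list shows neither transcript levels nor which part of a gene was removed, so these calls separate the genotypes at the locus but do not measure the deletion.

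**Figure D1:**
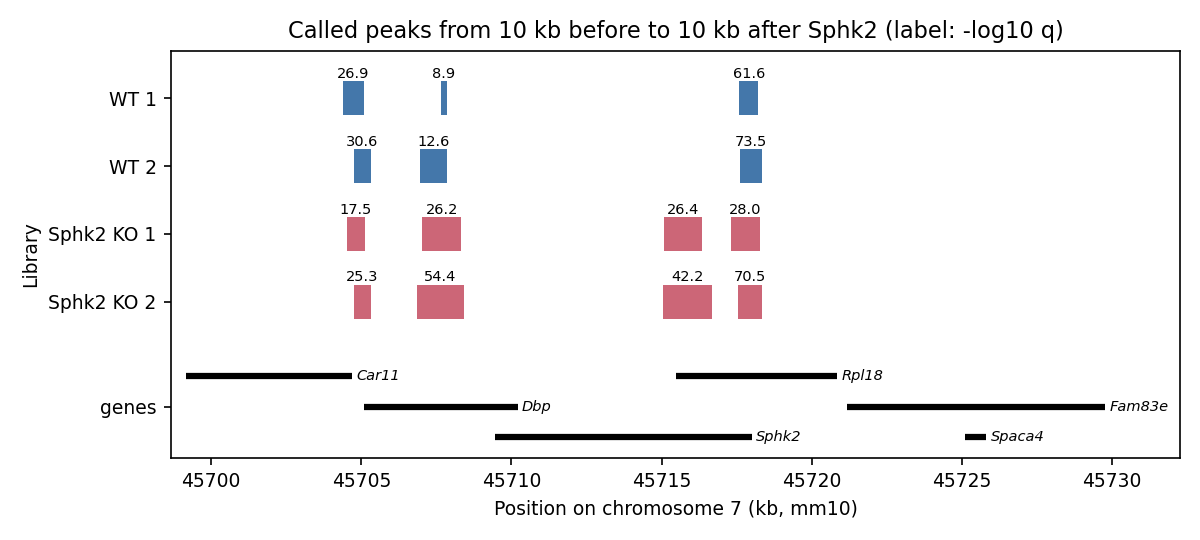
Called peaks around Sphk2 on chromosome 7 (x axis, position in kb, mm10) in each of the 4 libraries (y axis; WT blue, Sphk2 KO red), with the authors' −log10 q above each peak and gene extents as black lines. The peak starting at 45715043 in Sphk2 KO replicate 2 has a counterpart in Sphk2 KO replicate 1 and none in the WT libraries.

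The WT libraries held more called peaks than the Sphk2 KO libraries. The lists contained 31507 and 31843 peaks in WT and 20759 and 27446 in Sphk2 KO, or 31675 ± 238 against 24102.5 ± 4728 (mean ± SD, n = 2 each). Both WT values lay above both Sphk2 KO values, and a two-sided exact permutation test gave p = 0.333, the smallest value that 2 libraries against 2 allow. The order of peak numbers followed that of retained fragments. The peaks covered 18.4 and 20.6 Mb in WT and 13.5 and 19.1 Mb in Sphk2 KO. The base-pair Jaccard index was 0.609 between the WT libraries and 0.589 between the Sphk2 KO libraries, and ranged from 0.539 to 0.617 over the 4 pairs of unlike genotype. The mean of like pairs exceeded that of unlike pairs by 0.0190 (exact p = 0.333 over the 3 splits of the libraries, the smallest possible), so the test could not show whether the genotypes separated beyond the spread between replicates. This difference was -0.000409 without Sphk2 KO replicate 1.

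Overlapping peaks merged into 45299 regions, of which 16973 (37.5%) were called in all 4 libraries. A set of 2460 regions was called in both WT libraries and in neither Sphk2 KO library (WT-only), and 274 regions were called in both Sphk2 KO libraries and in neither WT library (Sphk2 KO-only). Together these 2734 regions outnumbered the regions private to the pairs of the 2 splits that mix genotypes, which totalled 1505 and 966. The same order held with the 20759 top peaks of every library, when the genotype split gave 954 WT-only and 526 Sphk2 KO-only regions, 1480 in all, against 610 and 529. WT-only regions were 8.98 times as many as Sphk2 KO-only regions with all peaks and 1.81 times as many with lists of equal length. The corresponding ratios within the mixed splits were 7.22 and 3.69 with all peaks and 3.07 and 2.27 with lists of equal length. Sphk2 KO replicate 1, the library with the shortest list, was the only library lacking a peak in 3258 regions, against 220 to 424 such regions for each of the other 3 libraries. Without Sphk2 KO replicate 1 the counts were 2712 WT-only and 4271 Sphk2 KO-only regions, and with either WT library left out WT-only regions numbered 9084 and 9298, since 1 library then stands for its group. Regions are not replicates, so no p-value was computed for the difference between genotypes.

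**Figure D2:**
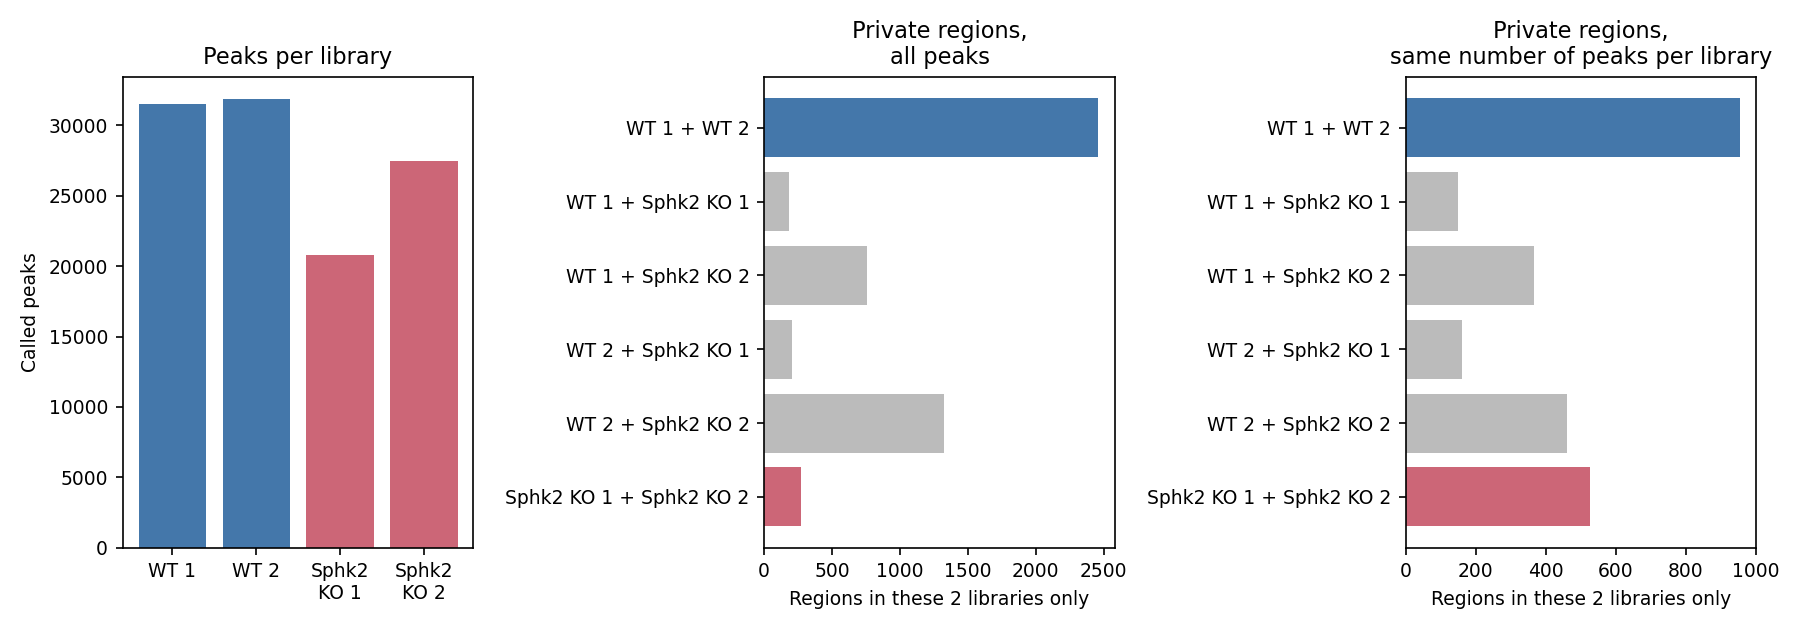
Number of called peaks per library (left, bars), and number of regions called in exactly 2 libraries for each of the 6 pairs, with all peaks (middle) and with the 20759 top peaks of every library (right). Blue marks WT, red Sphk2 KO and grey pairs of unlike genotype; with lists of equal length the like pairs hold 954 and 526 regions and each unlike pair between 150 and 460.

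The best-ranked WT-only regions included regions at interferon-induced genes. Each region is named here by the gene with the nearest end. The region at Ifit3, an antiviral protein gene induced by interferon, spanned 34582774 to 34583943 on chromosome 19, 153 bp from the gene end, with the authors' −log10 q of 40.9 and 63.9 in the WT libraries. At Gvin1, which encodes a large interferon-inducible GTPase, the region at 106215317 to 106215818 on chromosome 7 had values of 32.1 and 42.6. The region near Nrp1, a co-receptor for semaphorins and vascular endothelial growth factor, had values of 26.9 and 28.4. Regions inside genes were found at Gys1, glycogen synthase (24.7 and 29.8), and Gli1, a Hedgehog pathway transcription factor (23.0 and 33.9). Regions outside them lay nearest to Nek2, a mitotic kinase (24.0 and 28.3), Slc38a3, a glutamine transporter (23.5 and 32.3), and Ddx6, an RNA helicase (29.9 and 25.6). Iah1 and Irf2bpl were further members. The region ranked first lay 97.5 kb from its nearest gene end, that of the vomeronasal receptor gene Vmn2r87, and was 186 bp wide (−log10 q 94.1 and 92.9). WT-only regions were mostly weak calls, with a median −log10 q of 5.07 in WT replicate 1 and 6.11 in WT replicate 2, and 240 reached 10 in both libraries.

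The best-ranked Sphk2 KO-only regions lay on the chromosome that carries Sphk2. Of the 12 genes named by rank in this direction, 8 were on chromosome 7, against 2 of 12 (Gvin1 and Gys1) among WT-only regions. The strongest call was at Trim12a, a member of the tripartite motif family of antiviral factors (104314428 to 104316073, −log10 q 80.8 and 140). Regions near the related gene Trim30d (26.4 and 37.2), near Abhd2, a lipid hydrolase gene (38.4 and 68.7), near Otud7a, a deubiquitinase gene (26.5 and 49.0), in Sult2b1, a sulfotransferase gene for cholesterol (19.6 and 41.4), and in Dgat2, which makes triacylglycerol (11.2 and 22.6), were all on chromosome 7. So were Gm1966 and the region shared by Rpl18 and Sphk2. The Abhd2 and Otud7a regions lay outside these genes, 41058 and 55976 bp from their ends. Off this chromosome, the nearest genes were Gm13275, the adhesion molecule gene Cadm1 (17.2 and 27.6), Tmem267 and Asap1, a regulator of Arf GTPases (11.2 and 16.1).

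Among the 17 Sphk2 KO-only regions with a −log10 q of at least 10 in both libraries, 11 (64.7%) were on chromosome 7, compared with 6.75% of the regions called in all 4 libraries. The odds ratio was 25.3 (95% confidence interval 9.36 to 68.7, two-sided Fisher's exact test, p = 2.45e-08 after Benjamini-Hochberg adjustment over chromosomes). They spread from 45.7 to 106.7 Mb, a stretch of 60.9 Mb that starts at Sphk2. At the same strength, 17 of 240 WT-only regions were on chromosome 7 (odds ratio 1.05, adjusted Fisher's exact p = 1). For all 274 Sphk2 KO-only regions the odds ratio was 1.64 (29 regions, Fisher's exact p = 0.0206, adjusted p = 0.302). All 2460 WT-only regions were under-represented on chromosome 7 (120 regions, odds ratio 0.709, 0.584 to 0.860, adjusted Fisher's exact p = 0.00692). This was not particular to chromosome 7, since chromosome 19 had an odds ratio of 0.653 (62 regions, 0.502 to 0.851, adjusted Fisher's exact p = 0.0107). These tests treat regions as units and were chosen after the positions had been seen. Without Sphk2 KO replicate 1 the odds ratio of the strongly called regions was 2.52, with 37 of 243 on chromosome 7; without WT replicate 1 it was 5.14, without WT replicate 2 it was 4.31 and without Sphk2 KO replicate 2 it was 20.02. With the 20759 top peaks of every library it was 7.46, with 12 of 34 on chromosome 7.

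**Figure D3:**
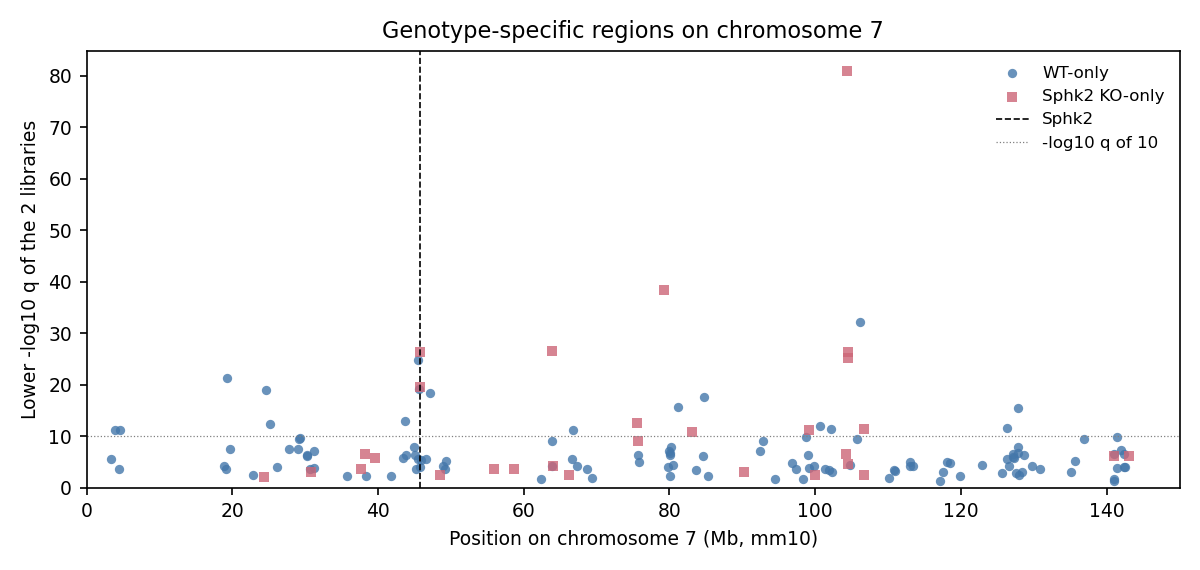
Genotype-specific regions along chromosome 7 (x axis, Mb, mm10) by the lower of the authors' −log10 q values in the 2 libraries that called them (y axis); blue circles are WT-only, red squares Sphk2 KO-only, the dashed line is Sphk2 and the dotted line a value of 10. The 11 red squares above the dotted line lie between 45.7 and 106.7 Mb.

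Fewer genes of the type I interferon response carried gene-end peaks in the Sphk2 KO libraries. Of 24 genes in this list, 21 had a peak within 1 kb of a gene end in each WT library, against 14 and 17 in Sphk2 KO replicates 1 and 2. Ifit3, Oas3 and Oas1a, sensors and effectors of antiviral defence, and Cxcl10, an interferon-induced chemokine, had one in both WT libraries and in neither Sphk2 KO library. Rsad2, Oas2 and Oasl2 lacked one in Sphk2 KO replicate 1 alone, while Ifit1, Irf7, Stat2, Usp18 and Bst2 had one in all 4 libraries. The 4 genes made 19.0% of the 21, compared with 2.70% of all other genes with a gene-end peak in both WT libraries (Fisher's exact p = 0.00228, Benjamini-Hochberg adjusted over 27 lists p = 0.0615). With the 20759 top peaks of every library the same 4 genes stood against 1.68% of other genes (Fisher's exact p = 0.000400, adjusted p = 0.0108), and with a −log10 q of at least 5 the adjusted exact p was 0.0189. By regions the list held 7 WT-only, assigned to Ifit3, Oas3, Ifit2, Cxcl10, Oas1a and Ifi204, and 0 Sphk2 KO-only regions. Oas3 had −log10 q values of 22.2 and 23.8 in WT, and Cxcl10 15.8 and 10.7. The gene-level test was added after the lists had been seen, and its adjusted p was between 0.0644 and 0.218 when any 1 library was left out.

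Monocyte and antigen presentation genes also had gene-end peaks at fewer genes in Sphk2 KO, as did all genes together. Over all genes, 10490 and 10693 had gene-end peaks in WT replicates 1 and 2 and 9317 and 10345 in Sphk2 KO replicates 1 and 2. Of 16 monocytic MDSC markers, 8 and 9 had gene-end peaks in WT and 4 and 6 in Sphk2 KO. Fn1, fibronectin, and Irf8, a transcription factor of the monocyte lineage, had one in both WT libraries and in neither Sphk2 KO library (2 of 8 genes, Fisher's exact p = 0.0188, adjusted p = 0.253). With all peaks the list held 7 WT-only regions, assigned to Klf4, Fn1, Irf8 and F13a1, and no Sphk2 KO-only region. Of 18 MHC class II and costimulation genes, 13 in each WT library and 10 and 11 in Sphk2 KO had gene-end peaks, and the 5 WT-only regions were assigned to Cd40, Cd86, H2-Oa and H2-Aa. Cd40 and Cd86 encode costimulatory molecules of antigen-presenting cells, and the other two encode MHC class II chains. In the gene-level test Cd40 and H2-Aa made 2 of 11 genes (Fisher's exact p = 0.0349, adjusted p = 0.314). With lists of equal length, MHC class II and costimulation genes with gene-end peaks numbered 10 and 10 in WT and 10 and 7 in Sphk2 KO. Monocytic markers then numbered 7 and 7 in WT and 4 and 6 in Sphk2 KO. With a −log10 q of at least 5 Cd40, Ctss and H2-Oa made 3 of 10 (adjusted Fisher's exact p = 0.0189), and with lists of equal length Cd40 alone made 1 of 9 (adjusted exact p = 0.714). Dendritic cell markers had gene-end peaks at 9, 9, 5 and 9 genes in WT replicates 1 and 2 and Sphk2 KO replicates 1 and 2, with 1 WT-only region, at Flt3. In the gene-level test 0 of 9 were private to WT with all peaks, and Clec10a and Irf4 made 2 of 7 with lists of equal length (adjusted Fisher's exact p = 0.0524) and with a −log10 q of at least 5 (adjusted exact p = 0.0589). Housekeeping genes had them at 18, 18, 18 and 19 of 20 genes, and genes silent in blood at 2, 4, 1 and 3 of 20. T cell markers, which would mark host T cells or EL4 tumour cells in the sort, stood at 5, 11, 4 and 4 of 20 genes, so WT replicate 2 differed from WT replicate 1. With a −log10 q of at least 5 the T cell list also passed the gene-level test, by Lat and Tox (2 of 5 genes, adjusted Fisher's exact p = 0.0482).

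Granulocytic MDSC markers were the list with the largest share of Sphk2 KO-only regions among lists with more than 2 group-specific regions. It held 5 WT-only regions, at Csf3r, Wfdc21, Il1r2 and Ltf, and 3 Sphk2 KO-only regions, at Il1r2 and Ltf, against 2076 and 217 regions assigned to any gene (Fisher's exact p = 0.0327, adjusted over 24 lists p = 0.785). Il1r2, a decoy receptor for interleukin 1, and Ltf, lactoferrin of neutrophil granules, thus had regions of both directions. Gene-end peaks at Ltf and at Hdc, histidine decarboxylase, were called in both Sphk2 KO libraries and in neither WT library (2 of 12 genes, against 0.217% of other genes, Fisher's exact p = 0.000354, adjusted p = 0.00956). No genotype-specific region was assigned to Hdc, and the Ltf region was weak, with −log10 q of 2.43 and 7.80. The call was lost with a −log10 q of at least 5, with lists of equal length and without any 1 library (adjusted p from 0.0517 to 0.393 over the 4 libraries). By regions, lists of equal length gave 1 WT-only and 8 Sphk2 KO-only regions (Fisher's exact p = 0.00124, adjusted p = 0.0273), at Il1r2, Ltb4r1, Trem1, Csf3r and Ltf, but 5 of the 8 had a WT peak in the full lists.

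**Figure D4:**
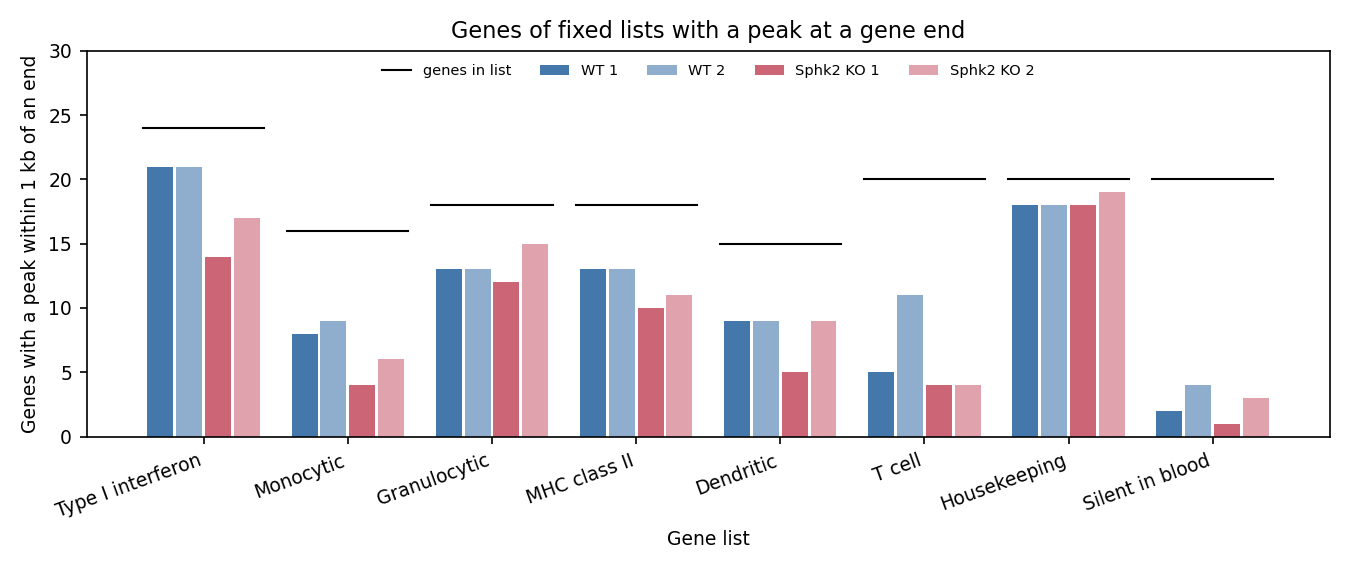
Number of genes with a called peak within 1 kb of a gene end (y axis) in 8 of the fixed gene lists (x axis), 1 bar per library (WT blue, Sphk2 KO red; darker bar, replicate 1), with the list size as a black line. Type I interferon genes stand at 21 in both WT libraries and at 14 and 17 in Sphk2 KO; housekeeping genes stand at 18, 18, 18 and 19.

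Genotype-specific regions were also assigned, by the nearest gene end within 100 kb, to lipid genes that bear on the purpose of the study. Acetyl-CoA and fatty acid synthesis genes had gene-end peaks at 23, 26, 21 and 23 of 32 genes in WT replicates 1 and 2 and Sphk2 KO replicates 1 and 2. They held 2 WT-only regions, both assigned to Elovl5, a fatty acid elongase, and no Sphk2 KO-only region. The better-ranked of the 2 lay outside the gene, 58741 bp from its end. Phosphatidylcholine and phospholipid genes held 9 WT-only regions over 7 genes, among them Pld1, a phospholipase D (−log10 q 8.69 and 12.3), Lpin1, a phosphatidate phosphatase (8.83 and 9.80), Lpcat1 and Agpat3, and 1 Sphk2 KO-only region, near Pisd. The Lpcat1 region lay outside the gene, 33224 bp from its end. Sphingolipid genes held 3 WT-only regions, in Acer1 and Cers4 and 31107 bp from Plpp3. They held 1 Sphk2 KO-only region near Degs1, the dihydroceramide desaturase gene (8.89 and 17.3). Sphingosine 1-phosphate receptor and transport genes held 3 WT-only regions, assigned to S1pr5 and Abcc1. Fatty acid oxidation genes held 4 WT-only regions, inside Acadl, Cd36 and Pparg and 64649 bp from Ppara. They held 1 Sphk2 KO-only region, also inside Pparg, a nuclear receptor of lipid metabolism. Cholesterol synthesis had 1 WT-only region and glycolysis 5, including Pfkp, Slc2a1, Pfkl and Pfkfb3. No list in this paragraph departed from the general ratio of directions (adjusted Fisher's exact p = 1 for each). An excess of WT-only regions could not have passed, since 36 with none of the other direction were needed.

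Inflammatory and effector genes also held more WT-only than Sphk2 KO-only regions, as did all genes together. The inflammatory cytokine list held 9 WT-only regions, among them regions assigned to Nfkb1 (−log10 q 13.8 and 24.3), Il6, Tnfaip3 and Icam1. It held 1 Sphk2 KO-only region, assigned to Il1b. The regions of Nfkb1, Il6, Tnfaip3 and Il1b lay outside these genes, 39485, 64824, 28658 and 37226 bp from their ends. MDSC effector genes held 6 WT-only regions, including the genes of the phagocyte oxidase Ncf1 (31.0 and 20.5), Cybb and Ncf4, and Ptgs2, and 2 Sphk2 KO-only regions, including a region near Cd84. Myeloid transcription factors held 11 WT-only regions, including Klf4, Irf8 and Bcl6, and 1 Sphk2 KO-only region at Runx1, which also had a WT-only region. Immediate early genes held 5 WT-only regions, assigned to Dusp1, Klf6, Fosl2 and Jun. The Dusp1 and Jun regions lay 18125 and 41427 bp from the gene ends. T cell markers held 7 and 1 (Satb1), macrophage markers 1 (Mertk) and 1 (Cd163), and cell cycle genes 3 and 0, at Cdkn1a, Ccnd3 and E2f2. Interferon gamma response (Gbp4), MHC class I processing (H2-K1), histone deacetylases and acetyltransferases (Hdac4) and genes silent in blood (Syt1) held 1 WT-only region each, and housekeeping genes 2 (Actb and Ywhaz). The Hdac4, Actb and Ywhaz regions lay outside these genes, 55421, 24492 and 49640 bp from their ends. B cell, NK cell, erythroid and mast cell, and endoplasmic reticulum stress lists held none. Over the 24 lists with a genotype-specific region, Fisher's exact test found 0 past an adjusted p of 0.05 and 1 (granulocytic) under an unadjusted 0.05. An excess of WT-only regions could not have passed in any list, since 36 regions with none of the other direction were needed and the fullest list held 12.

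Genotype-specific regions were mostly away from gene ends. A summit within 1 kb of a gene end was found for 29.5% (95% exact interval 29.0 to 30.04) and 29.6% (29.1 to 30.1) of WT peaks and for 38.8% (38.2 to 39.5) and 32.8% (32.3 to 33.4) of Sphk2 KO peaks. The share was 45.4% among regions called in all 4 libraries, 11.5% among WT-only regions (284 of 2460) and 8.03% among Sphk2 KO-only regions (22 of 274). The shares of WT-only and Sphk2 KO-only regions did not differ past the threshold (odds ratio 1.49, interval 0.9505 to 2.35, two-sided Fisher's exact p = 0.0858), but the call changed with each library left out. With 0.5 added to each count, the log2 odds ratio was 0.55 with all libraries, -0.55 without WT replicate 1 (Fisher's exact p = 0.0165) and -0.74 without WT replicate 2 (p = 0.000155 by the same exact test). It was 1.10 without Sphk2 KO replicate 1 (exact p = 4.99e-18) and 2.16 without Sphk2 KO replicate 2 (exact p = 4.68e-56).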

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

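The settings that leave out chromosome 7, require a −log10 q of at least 10, or take shares among regions in 2 or 3 libraries, the chromosome tests and the gene-level tests were chosen after seeing the data. Depth limits every count here, since a region is scored only as called or not called. WT-only regions numbered 1424 with a −log10 q of at least 5, 1001 with that threshold for presence alone, 954 with equal numbers of top peaks and 240 with a −log10 q of at least 10 for presence. Sphk2 KO-only regions numbered 176, 73, 526 and 17 under the same settings. With each library left out in turn, WT-only regions ranged from 2712 to 9298 and Sphk2 KO-only regions from 495 to 4271, because 1 library then stands for its group. WT-only regions outnumbered Sphk2 KO-only regions in each of these settings except without Sphk2 KO replicate 1. The number of lists past the adjusted threshold was 1, the granulocytic list, with equal numbers of top peaks, with peaks within 500 bp counted as present, without WT replicate 2, and as a share among regions in 2 or 3 libraries (Sphk2 KO-only, equal numbers of top peaks), and 0 in the other settings, leaving out a library giving 0 to 1.

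The log2 odds ratio of WT-only against Sphk2 KO-only regions at gene ends, with 0.5 added to each count, was 0.55 and reversed to -0.037 with a −log10 q of at least 5, -0.16 with that threshold for presence alone and -1.05 with a −log10 q of at least 10. It ranged from -0.74 without WT replicate 2 to 2.16 without Sphk2 KO replicate 2 over the libraries left out, with -0.55 without WT replicate 1 and 1.10 without Sphk2 KO replicate 1. The excess of similarity within genotypes reversed to -0.0180 as the share of the shorter list and ranged from -0.000409 to 0.0592 over the libraries left out. The log2 odds ratio of chromosome 7 among all Sphk2 KO-only regions, 0.71, reversed to -0.07 without Sphk2 KO replicate 1 and -0.12 without Sphk2 KO replicate 2, and was 0.40 and 0.33 without WT replicates 1 and 2. The causes were not tested.

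A paired sign test with the replicate number as a replicate block left the difference in peak numbers at -7572.5 (exact p = 0.5, the smallest for 2 pairs). Whether the replicate numbers pair the samples was not settled. The correlation of replicate differences across regions was 0.0332. Between genotypes, the mean Jaccard index was 0.589 for libraries of the same number and 0.571 for libraries of unlike number. Of the named regions, 40 of 75 WT-only and 18 of 23 Sphk2 KO-only stayed specific with equal numbers of top peaks. Over all settings, 42 values of the main comparisons kept their direction and size or call, 19 moved, 7 reversed and 2 gained a call. Of the values for single lists, genes and chromosome 7, 1503 kept theirs, 472 moved, 9 lost and 2 gained a call, and 2 reversed. The motif comparison and its alternatives were not run.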

Other observations

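The B cell and NK cell tests, the second T lineage list and the equal-length test of T cell genes below were set before their results were seen. The test without gene families was also set beforehand, and the other tests in this part were chosen after the results had been seen.

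In total 278 genes had gene-end peaks in both WT libraries and in neither Sphk2 KO library, and 22 genes had the reverse. The 22 included Ltf and Hdc among granulocyte genes, F2r, a thrombin receptor, Crispld2, and Arntl2, a circadian transcription factor. Of the 22, 5 were on chromosome 7 (Rasip1, Rpl18, Trim5, Trim12a and Trim30d), against 16 of the 278. The 4 mixed pairs had 7, 14, 88 and 157 such private genes. With equal numbers of top peaks the WT pair had 163, the Sphk2 KO pair 73 and the mixed pairs 20, 24, 53 and 66.

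The strongest peaks found only in Sphk2 KO cells lay on chromosome 7, over a stretch that starts at Sphk2. A shorter peak list as the whole account is argued against, since with equal numbers of top peaks the odds ratio for chromosome 7 among the strongly called regions was 7.46 (12 of 34 regions, 3.68 to 15.1, Fisher's exact p = 1.39e-06), against 25.3 with all peaks. Reads shared among tandem gene families such as the Trim genes are argued against as the whole account, since without such families it was 22.0 (6 of 10 regions, Fisher's exact p = 1.16e-05). A stretch of chromosome 7 inherited with the targeted allele, from the strain in which it was made, is a candidate explanation. It would also bring strong WT-only regions there, and their odds ratio in the stretch, 1.45 (0.678 to 3.09), left this open. The stretch was bounded by the Sphk2 KO-only regions themselves, so it left out the lower-coordinate side of Sphk2. Strongly called WT-only regions lay close to Sphk2 on that side, at 45.45 Mb (Gys1, lower −log10 q 24.7) and 45.59 Mb (19.2). Over the whole chromosome the strong WT-only regions had an odds ratio of 1.05 (0.641 to 1.73). All WT-only regions had 0.939 in the stretch (0.690 to 1.28) and 0.709 over the whole chromosome, beside 0.653 on chromosome 19. A direct effect of losing Sphk2 was not tested and stays possible.

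Type I interferon genes without gene-end peaks in Sphk2 KO may reflect a weaker interferon response in these cells, as a hypothesis. Peak calls do not measure that response, and it was not tested. Outside this list, Trim12a, of an antiviral family, and the related Trim30d had Sphk2 KO-only regions on chromosome 7. The interferon-inducible Gvin1, on the same chromosome, had a WT-only region. For the type I interferon list, the smaller number of peaks in Sphk2 KO as the whole account is argued against by lists of equal length (adjusted Fisher's exact p = 0.0108). An unrelated grouping of the libraries stays open: the other pairs had 0 such private genes of this list and the WT pair 4, but at most 0.266 was expected in any other pair, so the 0 decides nothing. A lower share of monocytic cells in the Sphk2 KO sort could give the same picture: the monocytic list in lists of equal length had an adjusted Fisher's exact p = 0.0524 with 2 of 7 genes, as did the dendritic cell list, too few to decide. In that setting 1 monocytic gene went the other way, with gene-end peaks in the Sphk2 KO pair only. By regions the monocytic list then held 4 WT-only and 1 Sphk2 KO-only. The sort by Gr1 and CD11b would admit both monocytic and granulocytic cells.

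T cell genes, among them Bcl11b, Cd28, Themis, Thy1 and Zap70, had gene-end peaks in WT replicate 2 and in no other library, 6 of 14 genes without one elsewhere against 2.87% of other genes (Fisher's exact p = 1.47e-06, adjusted p = 3.82e-05). The peaks at these 5 genes had −log10 q values between 2.34 and 6.11. The length of the list as the whole account is argued against, since WT replicate 1, with a list of nearly the same length, had 0 of 8, and equal numbers of top peaks gave 2 of 16 (Fisher's exact p = 0.0176, adjusted p = 0.458). Lymphocytes of every kind are argued against by B cell and NK cell markers, with 1 of 18 (Fisher's exact p = 0.0265 against the T cell list). T lineage cells, host or EL4, remain a candidate source although the sort for Gr1 and CD11b would remove them, and a second list of T lineage genes gave 2 of 20 (Lef1 and Tespa1, Fisher's exact p = 0.115) and does not decide it. The second list also gave 2 of 20 in Sphk2 KO replicate 2 alone (Cd4 and Sla2, Fisher's exact p = 0.0353) and 1 of 19 in WT replicate 1 alone (Skap1). It thus showed no excess particular to WT replicate 2.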
